A study of Mus musculus with 2 samples.

How the data were processed

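The series holds 2 arrays of mouse jejunum, the middle part of the small intestine. 1 array carries RNA from wild-type mice and 1 carries RNA from mice labelled XBP1 knock-out, and per the labels each RNA is a pool from 3 mice. Total RNA came from intestinal scrapings, per the labels' protocols, so epithelium, lymphocytes and other cells of the mucosa are measured together. Biotin-labelled cRNA made by in vitro transcription was hybridised to Affymetrix Mouse Genome 430 2.0 arrays, on which a gene is read by 1 or more probe sets of short oligonucleotides.

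The deposited values are intensity values on a linear scale, 1 per probe set. Per the submitters' processing notes they are MAS5 signals. The software version and the detection calls are not given in the sources used here. The trimmed mean of each deposited column, leaving out 2 percent at each end, was 500, so both arrays carry the authors' global scaling to a common target. Deposited signals ran from 0.17 to 87533 on the wild-type array and from 0.16 to 60153 on the other.

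The table lists 45101 probe sets, of which 64 are AFFX controls. The platform annotation gives 1 gene symbol for 34945 of the remaining 45037 probe sets and several symbols for 932, while 9160 are unnamed here. Symbols were updated by Entrez gene number through the RefSeq table of mouse assembly GRCm38.p6, which held 99.4% of the numbers behind probe sets with 1 symbol. Probe sets with several symbols were left out of every gene value. That table also gave the order of genes along a chromosome, used for the neighbours of Xbp1, and none of its coordinates are printed.

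Each array was first scaled so that the 75th percentile of its non-control probe sets equalled the geometric mean of both arrays' percentiles, with factors of 1.034 for wild-type and 0.967 for knock-out. Scaled signals below the 50th percentile over both arrays, 68.1 units, were then set to that floor, and log2 was taken. The log2 ratio is the knock-out-labelled array minus the wild-type array. A gene took the value of its probe set with the highest mean floored log2 signal. Of 18193 genes with a probe set of their own, 12826 exceeded the floor on at least 1 array and are called measured, and 10297 exceeded it on both. Where the dimmer array was at the floor, the ratio is a lower bound and is given as "at least".

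With 1 array per genotype there is no spread between replicates, and no p-value is given. Genes at least 2-fold higher or lower were counted. As a technical yardstick, log2 ratios of different probe sets of the same gene scattered with an SD of 0.33 over 3640 genes, a value that holds no variation between mice. For 43 gene lists, written from textbook knowledge before the data were examined, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. A list is described as above or below its matched range when its median lay outside the 2.5 to 97.5 percentiles of those random lists. Lists with fewer than 5 measured members have no percentile. This describes these 2 arrays and is not a test across animals.

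The genes named in the text follow a rule fixed before the data were examined. They are 11 genes of the unfolded protein response and of the main epithelial cell types, Xbp1 included. The rule adds the 12 genes with the highest and the 12 with the lowest ratio among genes that reached 4 times the floor on 1 array and whose other probe sets above 2 times the floor had the same sign. Genes without another such probe set, Atf5 and Muc2 among them, met this last condition without any check. The rule also adds up to 3 members at each end of each list. A few other list members are named as chosen after their values were seen.

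On simulated arrays built from the measured genes with a log2 noise SD of 0.3 per array, the 2-fold threshold recovered 17.6% of 68 genes changed by 1.5-fold, 77.8% of 63 changed by 2.5-fold and 97.1% of 69 changed by 4-fold. It also called 1.99% of unchanged genes with a mean signal above 2 times the floor. The changed genes were all drawn from genes with a mean signal above 4 times the floor. In the measured data the robust SD of log2 ratios reached 0.81 in a bin of dim genes. These percentages therefore need not hold for dim genes. Of 200 random simulated lists, with noise drawn independently for each probe set, 4.5% lay outside their matched range.

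The alternatives tried were the values as deposited, equal trimmed means, quantile normalization, loess on mean signal, a floor at the 25th or 75th percentile, the median over the probe sets of a gene, only probe sets without a suffix, thresholds of 1.5-fold and 3-fold, and a threshold of 3 robust SDs from genes of similar signal. Probe sets without a suffix are those whose identifiers do not end in _s_at, _x_at or _a_at. Such an identifier does not exclude sequence shared with other genes. A restriction to genes that reached 4 times the floor on 1 array and scalings that made the median of the hybridisation or the labelling spikes equal were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.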

Results

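Transcripts of the jejunal mucosa were measured on 2 arrays, 1 for a pool of 3 wild-type mice and 1 for a pool of 3 mice labelled XBP1 knock-out. XBP1 is the transcription factor that the endoplasmic reticulum (ER) stress sensor IRE1 activates by splicing its mRNA. The comparison asks which transcripts of the small intestine differ when XBP1 is missing. The median deposited signal over non-control probe sets was 72.5 in the wild-type pool and 62.2 in the knock-out-labelled pool, and 52.7% and 47.3% of their probe sets exceeded the signal floor. Among technical controls, the ratio of 3' to 5' probe sets was 1.65 and 1.31 for Actb and 0.93 and 0.84 for Gapdh, and the deposited signals of 18 probe sets for hybridisation spikes, which are usually added in fixed amounts before hybridisation, had a median log2 ratio of -0.69 between the arrays. For 27 probe sets for labelling spikes, usually added before labelling, the median was -0.23, and the 24 of them above the floor on both arrays ran from -0.68 to 0.31. Each value below comes from 1 array per pool, so no difference has a replicate check and the number of arrays limits the precision.

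The targeted gene was examined first. Xbp1 signal was 8143 in the wild-type pool and 6782 in the knock-out-labelled pool on its brightest probe set, a log2 ratio of -0.26. Its other probe sets gave 0.06, -0.15 and -0.24, all within the SD of 0.33 seen between probe sets of the same gene. With the hybridisation spikes made equal on both arrays, a scaling chosen after seeing the data, the ratio was 0.52. The labels do not say which part of the gene was deleted, and probe sets on this array type lie mostly towards the 3' end of transcripts. A probe set outside the deleted part still reads the remaining mRNA, so these values check neither label. Every direction given here therefore rests on the labels, and the second sample is called the knock-out-labelled pool throughout.

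Several Paneth cell genes and the goblet cell gene Muc2 were among the genes with the lowest ratios in the knock-out-labelled pool, while the goblet cell list as a group lay inside its matched range. As groups, targets of the PERK-ATF4-CHOP branch of the stress response and cell cycle genes were higher. Lyz1, the lysozyme of Paneth cells, was 9.59-fold lower, and Muc2, the main secreted mucin of the gut, was 10.1-fold lower. Atf5, a transcription factor induced when translation is inhibited under stress, was 18.8-fold higher and had the highest ratio among the genes eligible for naming. Neither Atf5 nor Muc2 had a second probe set of its own as a check. Ddit3, which encodes the stress-induced transcription factor CHOP, was 5.12-fold higher. Genes of absorptive enterocytes and of xenobiotic metabolism were lower as groups.

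Of 12826 measured genes, 288 were at least 2-fold higher and 652 at least 2-fold lower in the knock-out-labelled pool, so higher genes made up 30.6% of those past 2-fold. That share depended on the scaling. It was 41.9% for the values as deposited, with 382 genes higher and 530 lower, and 44.3% after loess, with 374 higher and 470 lower. The wild-type array was at or below the floor for 69 of the higher genes, and the knock-out-labelled array for 206 of the lower genes. The median log2 ratio of all measured genes was -0.11, and it was -0.02 for the values as deposited. With the spikes made equal, again chosen after seeing the data, the balance turned. The labelling spikes gave 711 higher and 321 lower genes and a median of 0.20, and the hybridisation spikes gave 2641 and 126 and a median of 0.62. Higher and lower therefore refer to the common 75th percentile of the arrays, and the matched ranges compare each list with genes of similar signal. Signals of the genes above the floor on both arrays correlated across genes with r = 0.967, where genes are not independent replicates, and 92.7% of measured genes lay within 2-fold.

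A second probe set reading above 2 times the floor was present for 83 of the higher genes, and the remaining probe sets of 78 of these had a median ratio of the same sign, which passed 2-fold for 40. For the lower genes the matching counts were 131, 123 and 72.

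Among the genes with the highest ratios, Rin1, an activator of RAB5, was 8.96-fold higher and Niban1, a gene induced by cellular stress, was 7.92-fold higher. Gsdmc2, a gasdermin of the intestinal epithelium, was 5.89-fold higher, and Pla2g4c, a cytosolic phospholipase, 5.22-fold higher. Tmem171 and Capn13, a calpain-type protease, were 5.08-fold and 4.67-fold higher, and Lrrc24 was at least 4.37-fold higher with the wild-type signal at the floor. The wild-type signal of Tmem171, 75.2, lay just above the floor. Among the lowest, Cubn, the receptor for the intrinsic factor and vitamin B12 complex, was 21.6-fold lower. Pdk4, an inhibitory kinase of pyruvate dehydrogenase, was 10.6-fold lower. Tmem238 was 10.5-fold lower, Naaladl1, an intestinal peptidase, 9.87-fold lower, Ces1f, a carboxylesterase, 9.09-fold lower, and Akr1c14, an aldo-keto reductase, 8.13-fold lower. In the knock-out-labelled pool Ces1f at 81.1 and Akr1c14 at 72.1 lay near the floor.

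**Figure D1:**
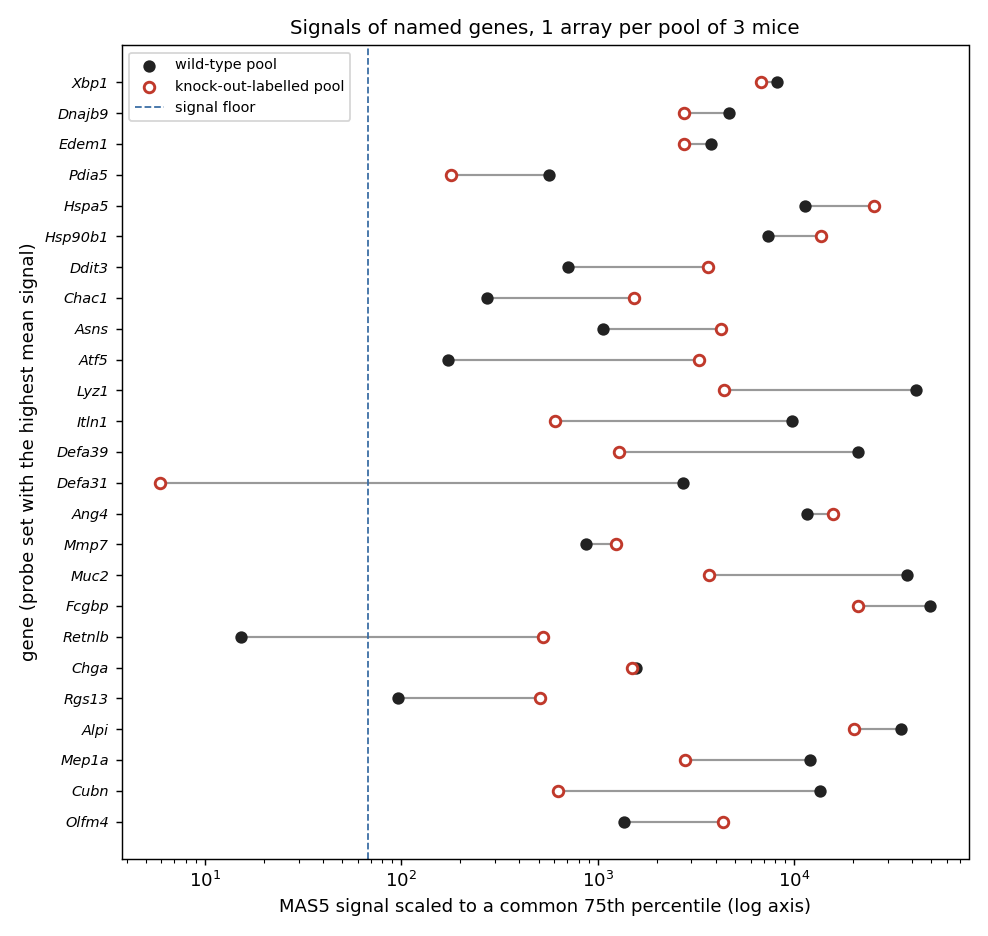
Scaled MAS5 signals on a log axis for 25 named genes, with filled points for the wild-type pool, open points for the knock-out-labelled pool and a dashed line at the floor of 68.1 units, 1 array per pool. Defa31 drops from 2704 to below the floor and Lyz1 from 41914 to 4373, while Ddit3 stands at 708 and 3628 and both Xbp1 points lie close together.

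Gene lists for the branches of the unfolded protein response were examined separately, and no test compared the branches. Of 35 measured PERK-ATF4-CHOP targets, genes that respond to the translational arm of the ER stress and amino acid response, 14 were at least 2-fold higher and 0 at least 2-fold lower, with a median log2 ratio of 0.83, above its matched range of -0.22 to 0.06. Chac1, a glutathione-degrading enzyme, was 5.58-fold higher, and Asns, asparagine synthetase, 3.95-fold higher. Chosen after their values were seen, the pseudokinase gene Trib3 had a log2 ratio of 1.90, the mitochondrial folate enzyme gene Mthfd2 1.80, and the tRNA synthetase genes Wars and Aars 1.44 and 1.40. At the other end of the list, Atf3 had a log2 ratio of -0.54, Ddit4 -0.77 and the hormone gene Stc2, at the floor in the knock-out-labelled pool, at most -0.99. The Ddit3 log2 ratio of 2.36 rests on its bright probe set, and a dim probe set of the gene gave 0.24. A second probe set of Stc2 gave 0.26.

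Genes of the secretory pathway that depend on XBP1 in other tissues, which cover translocation, glycosylation, folding and vesicle transport, lay mostly on the lower side. Of 61 measured members, 0 were at least 2-fold higher and 7 at least 2-fold lower, 48 ratios were below 0, and the median was -0.29, below its matched range of -0.20 to 0.02. The median was -0.19 for the values as deposited, again below the matched range, and 0.04 or 0.49 with labelling or hybridisation spikes made equal. In each of these settings the matched lists shift along with the median. Pdia5, a protein disulfide isomerase, was 3.16-fold lower, Creb3l2, a membrane-bound transcription factor of the secretory pathway, 2.37-fold lower, and Erp44, a thiol-dependent retention factor, 2.31-fold lower. Dnajb9, an ER co-chaperone, had a log2 ratio of -0.75, and Edem1, which feeds misfolded glycoproteins to degradation, -0.44, and these were 0.03 and 0.34 with the hybridisation spikes made equal. The highest members were Kdelr3 at 0.97, Gfpt1 at 0.67 and Sdf2l1 at 0.52.

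Chaperone genes assigned to the ATF6 branch did not move as a group. Their median over 20 members was -0.15, inside its matched range. On the probe set used for each gene, Hspa5 alone was at least 2-fold higher. Hspa5, the main luminal chaperone of the ER, stood at 11354 in the wild-type pool and 25572 in the knock-out-labelled pool, 2.25-fold higher. A second probe set went from 6076 to 17236, while the dimmest went from 1078 to 657, a log2 ratio of -0.71. Hsp90b1 had a log2 ratio of 0.89 and Manf 0.59, whereas Hyou1, P4hb and Herpud1 had -0.60, -0.61 and -0.75. A second, dimmer probe set of Hsp90b1 went from 2670 to 7945, a log2 ratio of 1.57 and thus past 2-fold. A second probe set of Herpud1 went from 3350 to 3475, a log2 ratio of 0.05.

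Sensors and signal components of the response had a median of -0.12 over 24 members, inside the matched range, with 1 member, Creb3l2, at least 2-fold lower. Ern1, which encodes IRE1 alpha, had a log2 ratio of 0.40, and Ern2, its form in mucus-secreting epithelium, -0.13. Atf6 had -0.81 and Ppp1r15b, a phosphatase subunit acting on eIF2 alpha, -0.76. Of 11 reported substrates of IRE1-dependent mRNA decay, 4 were at least 2-fold lower, and their median was -0.34, inside the matched range. Hgsnat, a lysosomal acetyltransferase, was 6.54-fold lower, Tapbp, which encodes tapasin, 2.61-fold lower, and Pmp22 2.33-fold lower, while Pdgfrb had a log2 ratio of 0.63. The median of this list lay below its matched range in 4 alternatives, at -1.12 with the floor at the 75th percentile, -0.32 after loess, -0.39 over probe sets without a suffix and -0.73 among genes that reached 4 times the floor, the last chosen after seeing the data.

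Paneth cell genes, which encode antimicrobial proteins of the crypt base, had a median log2 ratio of -0.48 over 9 measured members, below the matched range of -0.38 to 0.13, and 4 were at least 2-fold lower. Defa31, an alpha-defensin, was at least 39.7-fold lower with the knock-out-labelled signal at the floor. Defa39 was 16.4-fold lower and Itln1, the lectin intelectin, 15.9-fold lower. Lyz1, described above, was the remaining member past 2-fold. Mmp7, the protease that activates alpha-defensins, had a log2 ratio of 0.50 and Ang4, an antimicrobial ribonuclease, 0.45, and Habp2, near the floor, at most -0.03. The list held 38 genes, most of which had no measured probe set of their own. Alpha-defensin genes are nearly identical, so a single member's signal is uncertain. The 2 probe sets shared by several of them went from 15220 to below the floor and from 42874 to 5892, log2 ratios of at most -7.80 and of -2.86. The Paneth median was -1.78 over 8 members for the values as deposited, and among 6 members read by probe sets without a suffix it was -0.35, inside the matched range. Lyz1 resembles Lyz2 in sequence, and its probe set without a suffix, a dim one, gave -1.04.

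Goblet cell genes had a median of -0.20 over 26 members, inside the matched range, with 3 at least 2-fold lower and 1 at least 2-fold higher. Besides Muc2, which stood at 37565 and 3709, Klk1, a tissue kallikrein, was 3.64-fold lower and Fcgbp, a mucus glycoprotein, 2.31-fold lower. A dimmer probe set of Klk1 went from 893 to 1018, a log2 ratio of 0.19. Retnlb, a goblet cell cytokine with antimicrobial activity, was at least 7.71-fold higher with the wild-type signal at the floor. The transcription factor genes Creb3l4 and Creb3l1 had log2 ratios of 0.69 and 0.62.

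Hormone-producing enteroendocrine cells were represented by 22 genes with a median of -0.35, below the matched range of -0.32 to 0.12, and 2 were at least 2-fold lower. Pyy, the gene of peptide YY, was 3.84-fold lower and Scg5, a secretory granule chaperone, at least 2.56-fold lower. Gip had a log2 ratio of -0.93, and Chga, the general marker chromogranin A, -0.07. At the upper end, Cpe had 0.79 and Tac1 0.58. This list lay inside its matched range after quantile normalization, at -0.24. Tuft cell genes, markers of the chemosensory cells of the epithelium, had a median of 0.42 over 17 members, above the matched range of -0.36 to 0.16, with Rgs13, a regulator of G protein signalling, 5.31-fold higher and the actin-binding gene Avil at 0.89. Ratios were above 0 for 13 members and below 0 for 4, with Il17rb at -0.53, Ltc4s at -0.52 and Hpgds at most -0.36. Most members were dim. The 7 that reached 4 times the floor, a restriction chosen after seeing the data, had a median of 0.62, above the matched range. The tuft cell median was 0.95 with the hybridisation spikes made equal, inside the matched range of that setting.

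**Figure D2:**
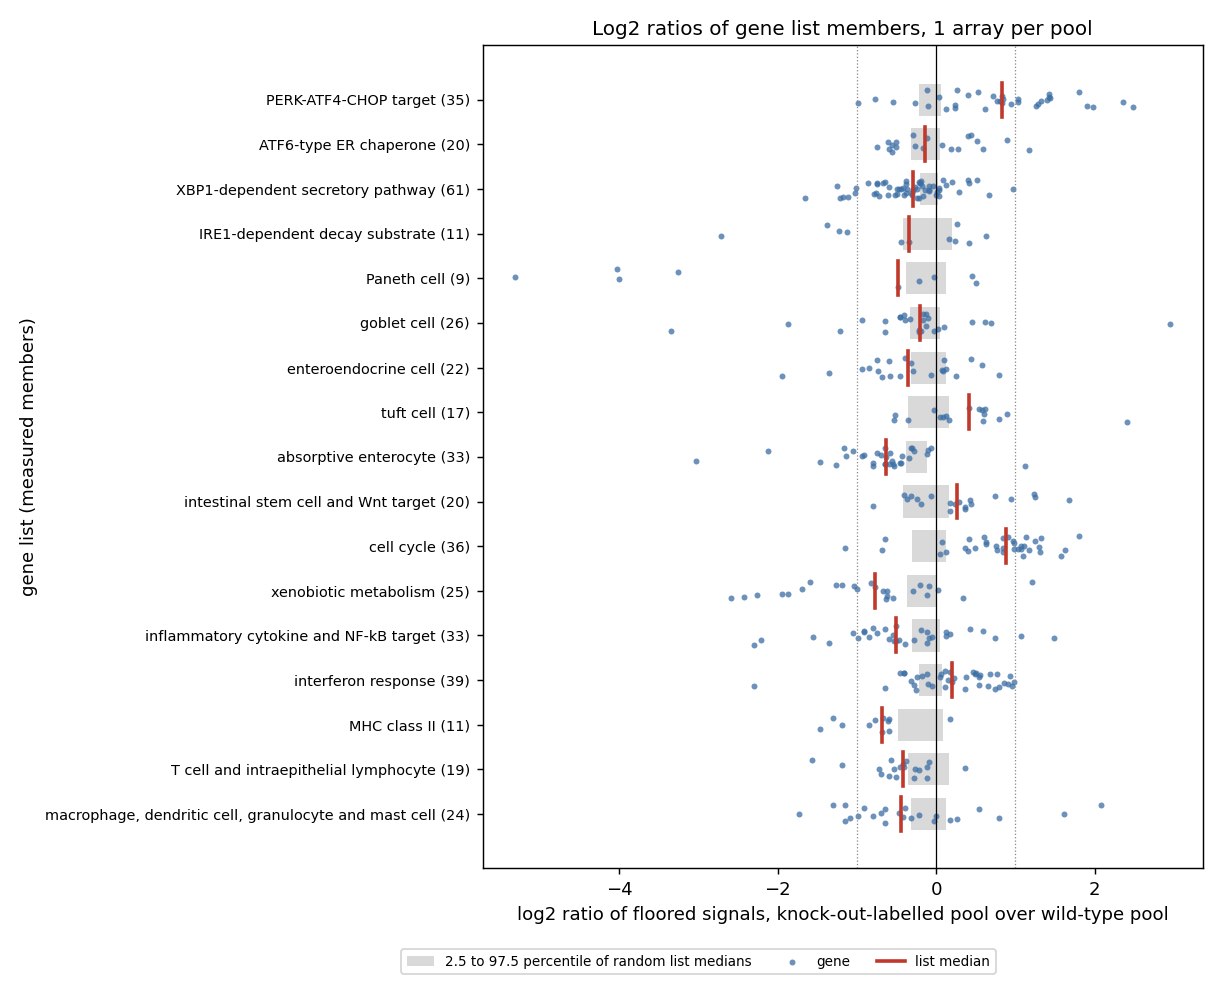
Log2 ratios of the members of 17 gene lists, knock-out-labelled pool over wild-type pool, with 1 point per gene, a red line at each list median, a grey band for the central range of random list medians matched on signal, and dotted lines at 2-fold. PERK-ATF4-CHOP targets and cell cycle genes have medians of 0.83 and 0.88 above their bands, absorptive enterocyte and xenobiotic metabolism genes have -0.63 and -0.77 below theirs, and the Paneth list splits into a far-lower group and members near 0.

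Absorptive enterocyte genes, which encode brush border enzymes, transporters and lipid-handling proteins, lay almost entirely on the lower side. Of 33 members, 32 had ratios below 0, 7 were at least 2-fold lower and 1 at least 2-fold higher, and the median was -0.63, below the matched range of -0.38 to -0.11. Xpnpep2, an aminopeptidase, was 8.19-fold lower, Mep1a, a meprin subunit, 4.33-fold lower and Treh, trehalase, 2.75-fold lower. Alpi, the intestinal alkaline phosphatase, stood at 35192 and 20290, a log2 ratio of -0.79 that became -0.44 after quantile normalization. The fructose transporter gene Slc2a5 was 2.17-fold higher, and Slc2a2 and Ada had -0.06 and -0.10. The list median was -0.34 after loess and -0.10 after quantile normalization, with lower ends of the matched ranges at -0.20 and -0.09. It was 0.15 with the hybridisation spikes made equal, where the matched lists shift along with it. For xenobiotic metabolism, 10 of 25 genes were at least 2-fold lower and 1 higher, with a median of -0.77. Ugt2b5, a glucuronosyltransferase, was 6.01-fold lower, and the cytochrome P450 genes Cyp2c29 and Cyp3a44 were 5.41-fold and 4.80-fold lower, while Cyp1a1 was 2.31-fold higher. Signals of Ugt2b5, Cyp2c29 and Cyp3a44 in the knock-out-labelled pool, 83.3, 75.8 and 78.6, lay near the floor.

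Cell cycle genes had a median of 0.88 over 36 members, above the matched range of -0.30 to 0.12, with 14 at least 2-fold higher and 1 at least 2-fold lower. Hmmr, a mitotic spindle gene, was at least 3.50-fold higher, Ccne1, which encodes cyclin E1, at least 3.09-fold higher, and Ube2c, of the anaphase-promoting machinery, 2.99-fold higher. Hmmr and Ccne1 were dim and their probe sets did not all show this, with ratios of 0.17 on another probe set of Hmmr and -0.12 on another of Ccne1. Foxm1, a transcription factor of mitotic genes, had a log2 ratio of -1.15 on the probe set used, at most -0.71 on another and at least 0.96 on a dim one, so its direction is unsettled. Genes of intestinal stem cells and Wnt signalling had a median of 0.27 over 20 members, above the matched range of -0.42 to 0.16, and 3 were at least 2-fold higher. Olfm4, a crypt base glycoprotein, was 3.19-fold higher, Bmi1, a polycomb gene, 2.38-fold higher and Lrig1, a receptor regulator, 2.36-fold higher, though a dim probe set of Lrig1 gave at most -0.29. Lgr5, the R-spondin receptor that marks crypt base stem cells, was at the floor in the knock-out-labelled pool with a log2 ratio of at most -0.79. With probe sets without a suffix the stem cell median was 0.17, inside its matched range.

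Inflammatory cytokines and targets of NF-kB had a median of -0.50 over 33 members, below the matched range of -0.30 to 0.05, with 5 at least 2-fold lower and 2 at least 2-fold higher. Cxcl10, a chemokine for activated T cells, was 4.92-fold lower, Ccl20, which attracts CCR6-bearing cells, 4.62-fold lower and Tnfaip3, an inhibitor of NF-kB signalling, 2.93-fold lower. Cxcl10 signal in the knock-out-labelled pool, 79.2, lay near the floor. Lcn2, which withholds iron from bacteria, was at least 2.81-fold higher and Saa3 2.09-fold higher, both dim. Interferon response genes had a median of 0.20 over 39 members, above the matched range of -0.21 to 0.07, with 0 at least 2-fold higher and Cxcl10 alone at least 2-fold lower. The guanylate-binding protein genes Gbp6 and Gbp7 had log2 ratios of 0.98 and 0.93, and Oas3 had -0.64. Immediate early and JNK-AP1 genes had a median of -0.19 over 27 members, inside the matched range, and the antiproliferative gene Btg2 was 2.12-fold lower. Epithelial antimicrobial and barrier genes went both ways, with 5 of 23 at least 2-fold higher, 1 lower and a median of -0.17 inside the matched range. Reg1 was 2.70-fold higher, while Ang was 2.32-fold lower and Reg3b, a lectin that binds bacteria, had -0.65.

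Markers of immune cells in the scraped mucosa differed between the pools as well, and so did MHC class II genes, which were listed as a process and not as cell markers. MHC class II genes had a median of -0.68 over 11 members, T cell and intraepithelial lymphocyte genes -0.42 over 19, and genes of macrophages, dendritic cells, granulocytes and mast cells -0.44 over 24, each below its matched range. The T cell median was -0.25, inside its matched range, with the floor at the 75th percentile. H2-Ea was 2.78-fold lower, the natural killer receptor gene Klrd1 2.29-fold lower, the complement gene C1qc 2.22-fold lower and Lyz2, the lysozyme of myeloid cells, 3.32-fold lower. Lyz2 resembles the brighter Lyz1, which was also lower, and Lyz1 signal on the Lyz2 probe set was not excluded. The mast cell protease genes Mcpt1 and Mcpt2 were 4.23-fold and 3.05-fold higher, both dim in the wild-type pool, with signals of 79.2 and 135.5. Cpa3, another mast cell protease gene, chosen after its value was seen, went the other way. It was dim and at the floor in the knock-out-labelled pool, with a log2 ratio of at most -0.65. B cell and plasma cell genes had a median of -0.23 over 16 members, inside the matched range, with the immunoglobulin A heavy chain gene Igha at -0.77. Over genes that reached 4 times the floor, a restriction chosen after seeing the data, the B cell median was -0.53 and below its matched range.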

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

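Data outside the gene comparison held further signals, read from probe sets without exactly 1 gene symbol and compared between the pools in the same way. Of 634 probe sets with several gene symbols above the floor, 12 were at least 2-fold higher and 31 at least 2-fold lower in the knock-out-labelled pool. The highest, shared by 3 genes, went from 3.84, below the floor, to 2880, a log2 ratio of at least 5.40, which exceeds the highest ratio of any gene eligible for naming, 4.24 for Atf5.

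Of 3023 probe sets above the floor that have no gene name here, 41 were at least 2-fold higher and 132 at least 2-fold lower. The highest of these went from 1389 to 7406, a log2 ratio of 2.41. At the other end, 1 probe set went from 47650 to 1111, a log2 ratio of -5.42, and another from 3444 to below the floor, a log2 ratio of at most -5.66. With 1 array per group, no sample can be set against others of its group.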

How the results depend on the processing

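The restriction to genes that reached 4 times the floor on 1 array and both scalings to spikes were chosen after seeing the data. Lower genes outnumbered higher ones in every alternative except 3. Hybridisation spikes made equal gave 2641 higher and 126 lower, labelling spikes 711 and 321, and the threshold of 3 robust SDs from genes of similar signal 516 and 199. Of these last, 421 higher and 0 lower lay in bins with a median signal up to 2 times the floor, where bin medians were as low as -0.63 and robust SDs as low as 0.10. The counts were 1139 higher and 2531 lower with the floor at the 25th percentile and 85 and 219 at the 75th, against 288 and 652. They were 162 and 337 among genes that reached 4 times the floor, 1005 and 2093 at 1.5-fold and 55 and 135 at 3-fold. The trimmed means gave 378 and 531 and quantile normalization 360 and 508. All 288 higher genes also passed 2-fold for the values as deposited and after loess, and of the 652 lower genes 530 and 470 did. Undoing the scaling raises the ratios of genes above the floor. For the deposited values, the result for the higher genes was therefore nearly fixed beforehand.

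The medians of cell cycle genes, PERK-ATF4-CHOP targets and absorptive enterocyte genes stayed on their side of the matched range in every alternative, though after quantile normalization the enterocyte median was only just below its range, at -0.10. The values as deposited, equal trimmed means and scalings to spikes each shift the ratios of all genes above the floor by a constant. They can change signs, while the place of a list against its matched range is nearly fixed beforehand and says little on stability. Loess removes a trend with mean signal, for which the matching already allows. With hybridisation spikes made equal the median was 0.33 for enteroendocrine, 0.15 for absorptive enterocyte, 0.49 for XBP1-dependent, 0.28 for inflammatory, 0.10 for MHC class II, 0.35 for T cell, 0.32 for myeloid, 0.02 for proximal, 0.09 for ileal, 0.43 for cholesterol and 0.01 for xenobiotic genes. In that setting pancreatic acinar genes had 0.34 and tuft cell genes 0.95, both inside, and Xbp1 had 0.52. With labelling spikes made equal the XBP1-dependent median was 0.04. Over probe sets without a suffix the Paneth median was -0.35 and the stem cell median 0.17, both inside their ranges, with fewer members measured. The enteroendocrine median moved inside its range after quantile normalization, at -0.24, and with the floor at the 25th and 75th percentile, at -0.30 and -0.29. The stem cell median with the floor at the 75th percentile was 0.29, inside its range. The ribosomal protein median changed sign, from -0.07 to 0.02 for the values as deposited, 0.02 with equal trimmed means, 0.20 after quantile normalization, 0.11 after loess, and 0.71 and 0.25 with hybridisation and labelling spikes made equal, and lay above its matched range each time. Apart from the scalings to spikes, the cause was not tested for these. Of all list medians under the alternatives, 189 stayed outside the range on the same side, 213 stayed inside, 20 moved inside, 14 moved outside and 0 crossed to the other side. These counts include the settings that shift ratios by a constant, so they overstate stability. Counted over the same medians, 79 changed sign, 60 of them from 18 lists that lay inside their range. Of the values of the 11 genes named in every case, 105 moved by less than 0.33 and 14 by more, 11 of them with hybridisation spikes made equal. No paired analysis was possible because each group holds 1 array. Signals near the floor limit what can be read, since 166 of the higher and 400 of the lower genes had a mean signal up to 4 times the floor.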

Other observations

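All tests of explanations in this part were chosen after the result was seen. Of the 40 gene lists with enough measured members, 6 lay above and 13 below their matched range. By chance 2.0 would be expected outside if the genes within a list varied independently. Genes of the same cell type or process need not do so, and this comparison is therefore no test against chance. In the list of fatty acid and triglyceride synthesis, Dgat2, which makes triglycerides, was 6.77-fold lower and the desaturase gene Scd2 3.24-fold higher, with 0.26 on a dim probe set of Scd2, while the median of 20 members was -0.07, inside its range. Among 23 genes of PPAR alpha and fasting, Angptl4, a lipase inhibitor, was 5.73-fold lower and Acot2, a mitochondrial thioesterase, 3.44-fold higher, with a median of -0.17 inside the range. Cholesterol synthesis genes had a median of -0.35 over 20 members, below the range, and with probe sets without a suffix the median was -0.11 and inside the range. Their regulator Srebf2 had log2 ratios of -1.04 and -0.06 on its probe sets. Phosphatidylcholine and ethanolamine synthesis genes had -0.12 over 14 members, with 0 past 2-fold in either direction. The lysosomal membrane gene Lamp1, in the autophagy list with a median of -0.26, was 5.27-fold lower. Among circadian genes, with a median of -0.29, Dbp was 2.90-fold lower and Per3 at least 2.79-fold lower. Autophagy and circadian medians lay inside their ranges.

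Oxidative phosphorylation genes had a median of -0.24 over 48 members, inside the range, with 0 past 2-fold. Ribosomal protein genes had -0.07 over 38 members with 0 past 2-fold, above the range, and the sign of that median depended on the scaling, being 0.02 for the values as deposited. Medians inside the range were also found for genes of NRF2 and glutathione defence, -0.03, apoptosis, -0.12, lineage transcription factors and Notch, -0.11, heat shock, -0.04, and housekeeping, 0.01. In these lists the pro-apoptotic gene Bcl2l11 was 2.39-fold lower and its other probe sets gave -1.70 to -0.39, the chaperone genes Hsph1 and Hspd1 were 2.29-fold and 2.10-fold higher, the transporter gene Abcc3 was 2.23-fold higher, and the transferrin receptor gene Tfrc was 2.90-fold higher. Bhlha15, which encodes the secretory cell factor MIST1, had a log2 ratio of -0.92. The brightest housekeeping genes, B2m, Actb and Eef1a1, had log2 ratios of -0.71, -0.52 and -0.41, while 6 of 12 measured members were above 0. In the brightest of the 20 bins of measured genes the median was -0.27. Lower ratios were thus common among very bright genes, to which Alpi, Reg3b and Igha belong. Genes of smooth muscle and fibroblasts had a median of 0.08 over 18 members, endothelial genes -0.15 over 11 and genes of enteric neurons and glia -0.45 over 7, all 7 below 0, each list inside its range. Pancreatic acinar genes had -0.50 over 11 members, below the range, with colipase, Clps, 3.20-fold lower, and -0.21, inside the range, for the values as deposited. Adipocyte genes had 4 measured members with a median of -0.21, and erythrocyte genes 3 with 0.07. The Y-linked genes Eif2s3y, Kdm5d and Uty had log2 ratios of 0.17, 0.29 and -0.03 and signals above the floor in both pools. Xist went from 117 to below the floor on its brightest probe set, a log2 ratio of at most -0.78, and its other probe sets were below the floor in both pools. The sex-linked list of 4 measured genes had a median of 0.07. Of 50 measured genes neighbouring Xbp1 in the gene order of the RefSeq table, 25 on each side, 2 were at least 2-fold higher and 0 lower, 4.0% against 7.3% of all measured genes.

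Cell cycle genes were higher while absorptive enterocyte genes were lower. A bias between the arrays that depends on signal would move genes of similar signal alike. The cell cycle median of 0.88 lay above the range of lists matched on signal, -0.30 to 0.12. This argues against such a bias as the whole cause for cell cycle genes. Their lowest median over loess and quantile normalization, 0.93, adds little, because the matching already allows for a trend with signal. For absorptive enterocyte genes a bias of this kind stays open, since the median was -0.34 after loess but -0.10 after quantile normalization, at the edge of a matched range starting at -0.09, and medians over resampled members had a central range of -0.44 to -0.05. A difference in the position of the sampled pieces along the intestine stays open too. Genes of the proximal small intestine and of the ileum had medians of -0.60 over 13 and -0.65 over 14 members, a difference of -0.05. A shift in position would part them, but the proximal list shares Lct, Slc5a1 and Fabp1 with the enterocyte list, and the ileal list shares Mep1b. Lower enterocyte genes would lower both lists, so the small difference cannot decide. Members of both lists went each way. In the proximal list 4 ratios were above 0, with Onecut2 at 1.07, Slc40a1 at 0.95 and the dim Pdx1 at 0.66. The other 9 were below 0, with Pdk4 at -3.40. In the ileal list 3 were above 0, with Car4 at 1.25, and 11 below. Cubn and Pyy, named above as lower, belong to the ileal list. The proximal list lay inside its range after quantile normalization, at -0.12. A larger share of crypt in the scraping may also contribute, as the stem cell median was 0.27, yet Paneth genes, which share the crypt base, were lower, and their lower signals cannot be told apart from an effect of genotype in this design.

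PERK-ATF4-CHOP targets were higher as a group. Their median of 0.83 lay above the range of lists matched on signal, -0.22 to 0.06. This argues against a bias between the arrays that depends on signal as the whole cause. The lowest median over loess and quantile normalization, 0.90, adds little, because the matching already allows for a trend with signal. Whether a different mix of cells in the scraping contributes was not tested. A stress response to the loss of XBP1 remains a hypothesis that 1 array per genotype leaves untested.

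The 8 measured probe sets of H2-D1, a classical MHC class I gene chosen after its values were seen, moved apart, 6 lower and 2 higher, from -1.16 to 1.46. Their SD was 0.90, and 3 of 179 genes with at least 5 measured probe sets, H2-D1 included, had an SD that large. Since the gene was picked for this divergence, ordinary disagreement between probe sets stays open. Different MHC haplotypes in the pools are another candidate explanation. The 7 other H2 genes with several probe sets had a median SD of 0.20, at the 33.6 percentile of random gene sets, but these are too few and differ too much in polymorphism to decide. Signal shared with near-identical class I genes may also be involved and cannot be told apart here, because only 1 of the probe sets is without a suffix.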
